A study of Drosophila melanogaster with 22 samples.

How the data were processed

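RNA was measured in Drosophila melanogaster cell lines and in 1 sample labelled as adult ovary. Per the labels' protocols, libraries were made from 200 ng of RNA with ScriptSeq v2 after Ribo-Zero depletion. The 8 count files as deposited by the authors hold raw read counts per feature. Per the submitters' processing notes, reads were mapped with TopHat2 and counted with HTSeq on builds dm3 and BDGP5, with no versions given. The 6 knock-down tables hold normalised mean counts per group, log2 fold changes with their standard errors, Wald statistics, p-values and adjusted p-values, made by the authors with DESeq2 and used as deposited. Each table lists 15089 genes, of which 454 to 486 have no values. Each count file lists 15293 features, of which 15253 are gene features and 40 are strands of piRNA clusters, and 15074 gene features were matched to a current symbol. Reads of antisense, overlapping or paralogous features may be assigned to the wrong one. All columns of values per sample were used.

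Samples were grouped by the labels into 12 groups. The groups with count files were OSS (1 library), the library labelled ovary (1), RasV12 (2), untreated WRR-1 of passage 154 (2) and GFP dsRNA (2). The untreated WRR-1 libraries of passages 111 and 112 and all knock-down libraries other than GFP have no count file, and knock-downs are known only through the authors' deposited tables. The title of the 2 piwi knock-down samples names argonaute 3, while their description and protocol name piwi. Total counts per library ran from 9307797 to 59965239.

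Differential expression was tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood fit and F test, group as the only term) in R 4.3.3, on all 8 libraries, so that groups with 1 library borrowed the spread of the others. Of the features 13163 were tested, with a common biological coefficient of variation of 0.45 and a median of 4.42 prior degrees of freedom. Genes were called at an adjusted p below 0.05 (Benjamini-Hochberg). SE is the log2 fold change divided by the square root of F. Levels are CPM scaled by TMM factors. A fold against a group without counts was computed against a floor of 3 counts per library and is a lower bound. For 1 to 3 counts the ratio is given with a 95% counting interval.

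Lists of genes were tested with camera in limma 3.58.1 on log CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over 24 lists and 5 comparisons. The lists were piRNA factors (shared, somatic and germline), other small RNA factors, ovarian soma, germline, chorion and yolk, muscle, neural, hemocyte, fat body, epithelium, Hippo, Ras and MAPK, JAK/STAT, JNK, immune, ecdysone, DNA replication, mitosis, heat shock, dosage and sex, glycolysis, and extracellular matrix. fry tests only whether a list moves one way on balance. The comparisons, lists, named genes and most alternatives were fixed before the data were examined.

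Named genes followed a rule. It took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a symbol, a mean CPM of at least 20 in the higher group and no overlap between libraries, or fewer where space was short. It took every measured member of the piRNA lists for WRR-1 against RasV12, up to 4 called members of each list with 3 or more, the targets of the knock-downs, and wts and Ras85D. From each knock-down table it took the 5 genes up and 5 down with the largest change at an adjusted p below 0.05 and a mean of at least 50, and 5 genes shared by the piwi, zuc and armi tables, with a tie for the last place kept whole. Cluster strands, the levels of single oocyte and eggshell genes, and values of named genes in further tables were chosen after their values were seen.

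Alternatives were RLE factors, the DESeq2 1.42.0 Wald test, no filter on low counts, CPM of at least 1 in at least 2 libraries, leaving out each replicate, only the 4 libraries compared, a replicate block, GFP dsRNA libraries in place of untreated ones, an adjusted p below 0.01, and a log2 fold change above 1. mRNA features only and leaving out the library labelled ovary were added after seeing the data. For the knock-down tables, another pseudocount, another tool, leaving out libraries and pairing were not run, since only group means were deposited. Overlaps of tables were set against independent lists and 20 simulations of unchanged groups with shared controls. In these, each variance was split equally into a shared and a separate part.

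The test was tried on counts simulated from these libraries. Of genes changed 4-fold, it recovered 59.7% for WRR-1 against RasV12, 28.4% against OSS, 43.3% against the library labelled ovary, 34.3% for RasV12 against OSS and 67.2% for GFP dsRNA. At 2-fold it recovered 5.97%, 0%, 5.97%, 0% and 8.96%, and at 16-fold 100%, 95.5%, 95.5%, 97% and 100%. False calls numbered 0 of 110, 1 of 83, 3 of 99, 6 of 93 and 9 of 126. A list shifted 8-fold ranked 1, with 2 lists called. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.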

Results

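RNA sequencing after ribosomal RNA depletion covered 22 Drosophila melanogaster samples in 12 groups. Counts per gene were deposited for 8 libraries, and group means with fold changes were deposited for 6 knock-downs. The 8 libraries comprised 1 of OSS cells, a line of ovarian somatic sheath cells, and 1 labelled as adult ovary that carried the wts-RNAi and RasV12 transgenes without a GAL4 driver. A pair of libraries came from RasV12 lines, which express activated Ras. Another pair came from untreated WRR-1 cells of passage 154, a line that combines activated Ras with RNAi against the Hippo kinase gene wts, and a further pair from WRR-1 cells given dsRNA against GFP. The RasV12 libraries were of separate lines, R3 at passage 77 and R7 at passage 68. Total counts were 9307797 for OSS, 39402776 for the library labelled ovary, 19989230 for R3 and 44076726 for R7. They were 59965239 and 35395338 for the untreated WRR-1 libraries and 15454750 and 33496887 for the GFP dsRNA libraries. Ribosomal RNA took 34.4% of the counts of R3 and 8.28% to 14.9% of the others. snoRNAs took 14.8% of the counts of R7 and 0.458% to 1.79% of the others. All levels given as CPM were scaled with TMM factors, and 13163 features were tested.

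The targeted genes were read first, since they check the labels. wts stood at 164 and 139 CPM in the untreated libraries labelled WRR-1 and at 50.4 and 57.4 CPM in the RasV12 libraries (log2 fold change 1.49 ± 0.28 SE, adjusted p = 0.0121, n = 2 and 2). Without WRR-1 replicate 1 the log2 fold change was 1.28, with an adjusted p of 0.0696. wts lay at 87.1 CPM in OSS, at 163 CPM in the library labelled ovary and at 182 and 173 CPM in the GFP dsRNA libraries. The level of wts was thus not lower, as the RNAi named in the label would have it, and the libraries are called labelled WRR-1 throughout. No line matched but for the RNAi gave a baseline, and reads of the construct were not told apart from those of the gene. The level therefore does not show whether the RNAi worked. Ras85D, the endogenous gene and the transgene counted together, stood at 1190 and 930 CPM in the untreated libraries labelled WRR-1, at 588 and 1230 CPM in RasV12 and at 881 and 878 CPM after GFP dsRNA. It lay at 85.2 CPM in OSS and at 1260 CPM in the library labelled ovary.

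The comparison of the untreated libraries labelled WRR-1 with the RasV12 libraries asked what sets cells with wts RNAi and activated Ras apart from cells with activated Ras alone. Line and passage differed between these groups along with genotype, so no difference can be assigned to wts RNAi. Some genes typical of the ovarian soma had next to no reads in the RasV12 libraries, although the list of such genes was not called (7 of 21 members higher, 2 lower and 12 not called; camera adjusted p = 0.115). tj, a Maf factor gene of somatic gonad cells, stood at 291 and 495 CPM in the libraries labelled WRR-1 and at 0 and 0.0342 CPM in RasV12 (13.89 ± 0.75 SE, adjusted p = 0.00042, n = 2 and 2). The ratio was 22900, with a counting interval of 2900 to 639000. Wnt4, which encodes a ligand needed in the ovarian soma, stood at 271 and 572 CPM and was at least 2870-fold higher than in RasV12, where both libraries had 0 counts. dec (listed as dec-1), an eggshell gene of follicle cells, was 2120-fold higher (10.87 ± 0.58 SE, adjusted p = 0.00042). The sex determination gene dsx stood at 219 and 447 CPM against 0.445 and 1.16 CPM in RasV12 (8.62 ± 0.69 SE, adjusted p = 0.000636).

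Further genes without a count in RasV12 included Gasp, a chitin-binding protein gene, at least 372-fold higher, and the channel gene trpl, at least 311-fold higher. The transcription factor genes bin and esg were at least 283-fold and at least 235-fold higher. abd-A, a Hox gene, had 1 count in the RasV12 libraries and a ratio of 8530 (counting interval 1020 to 225000). drd (listed as lwf), needed in the adult gut, had a ratio of 3900 (592 to 130000). Mp20, a muscle protein gene, was at least 167-fold higher, but its level rested on WRR-1 replicate 1, at 46.6 CPM against 2.56 CPM in replicate 2. Floors of 3 counts per library set these bounds, and intervals and bounds covered counting error only.

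Other genes were higher in RasV12. twi, the mesoderm determinant, stood at 195 and 125 CPM in RasV12 and at 0.0993 and 0 CPM in the libraries labelled WRR-1 (fell by 11.25 on the log2 scale, SE 0.99, adjusted p = 0.000884). The phagocytosis receptor gene NimC4 stood at 371 and 326 CPM in RasV12 against 0.0709 and 0.248 CPM (fell by 11.21, SE 0.67, adjusted p = 0.00042). The basement membrane genes Col4a1 (listed as Cg25C), vkg and SPARC (listed as BM-40-SPARC) were 79.9-fold, 235-fold and 10.8-fold lower in the libraries labelled WRR-1. The channel gene CngA (listed as CG42701), the GATA factor gene pnr and the homeobox gene hth were 2630-fold, 460-fold and 422-fold lower. firl (listed as CG14946), the esterase gene alpha-Est1 and the cytochrome gene Cyp4p2 were lower as well. Ldsdh1 (listed as CG2254) and the rRNA pseudogene 5SrRNA-Psi:CR33363 were carried by R7, with 98.7 and 85.7 CPM against 0.254 and 0.509 CPM in R3. Without R7 the adjusted p of Ldsdh1 was 0.208.

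**Figure D1:**
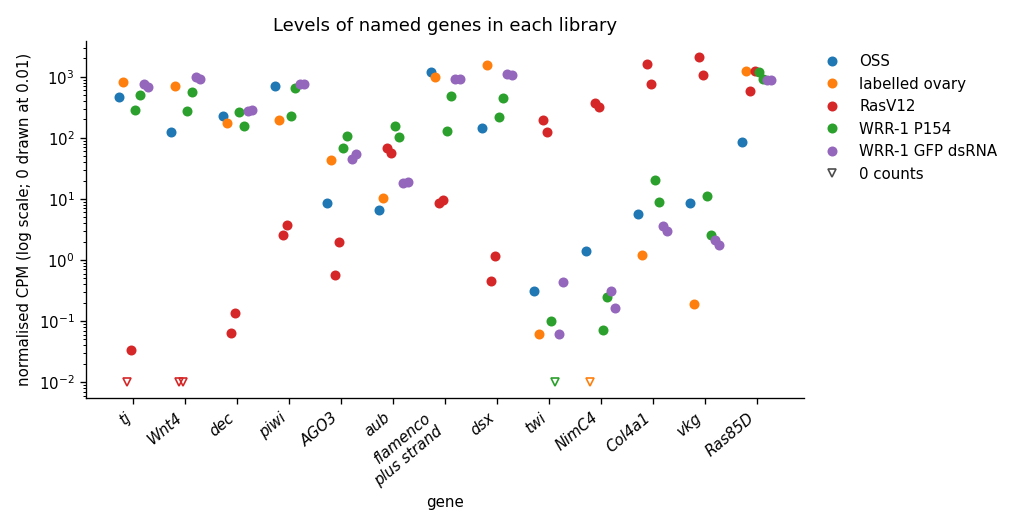
Normalised CPM on a log axis of 13 named genes in each of the 8 libraries, with 1 point per library and open triangles for 0 counts, drawn at 0.01. tj, Wnt4, dec, piwi, AGO3, flamenco and dsx were lowest in both RasV12 libraries, whereas twi, NimC4, Col4a1 and vkg were highest there.

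Of the PIWI genes, piwi (CG6122) stood at 224 and 650 CPM in the libraries labelled WRR-1 and at 2.61 and 3.77 CPM in RasV12, 137-fold higher (7.09 ± 0.66 SE, adjusted p = 0.00107, n = 2 and 2). AGO3, a PIWI gene of the germline, stood at 67.9 and 106 CPM against 0.572 and 1.99 CPM (6.02 ± 0.62 SE, adjusted p = 0.00143). aub, the third PIWI gene, stood at 157 and 103 CPM against 67.0 and 55.6 CPM (1.09 ± 0.31 SE, adjusted p = 0.0412). The call of aub was lost with RLE factors (adjusted p 0.0606) and without any 1 of 5 libraries. Its adjusted p was then 0.0949 without RasV12 replicate 2, 0.219 and 0.0636 without WRR-1 replicates 1 and 2, and 0.121 and 0.137 without GFP dsRNA replicates 1 and 2. With the GFP dsRNA libraries in place of the untreated ones, aub was lower than in RasV12 (log2 fold change −1.72, adjusted p = 0.00565).

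The list of piRNA factors shared by soma and germline had 18 members tested, of which 5 were higher, 0 lower and 13 not called (6 higher and 0 lower when adjusted over the list alone). The called ones were piwi, the helicase gene armi (2.05 ± 0.38 SE), the silencing factor genes Panx (2.68 ± 0.45 SE, listed as CG9754) and mael (1.85 ± 0.40 SE), and the mitochondrial scaffold gene Gasz (1.21 ± 0.28 SE, listed as CG2183). Not called were zuc (0.05 ± 0.45 SE, listed as CG12314), vret, shu, Hen1, arx, nxf2, egg, wde, mino, papi (0.83 ± 0.26 SE, adjusted p = 0.0561), squ, Su(var)205 and daed, with log2 fold changes between −0.47 and 0.83. zuc, shu and squ changed sign with RLE factors, to −0.05, −0.07 and −0.06. The 3 somatic factors measured, tj, fs(1)Yb (−0.28 ± 0.39 SE) and SoYb (1.14 ± 0.54 SE), included 1 called gene, tj. Of 13 germline factors, 10 were higher, 0 lower and 3 not called, with 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00472, and 0.602 with an estimated correlation). They were AGO3, rhi (33.6-fold, interval 10.2 to 310), del (2.36 ± 0.47 SE), krimp (2.24 ± 0.48 SE), cuff (2.17 ± 0.60 SE), moon (2.01 ± 0.47 SE), spn-E (1.78 ± 0.35 SE), Nxf3 (1.69 ± 0.48 SE), tapas (1.47 ± 0.43 SE) and aub. Over 14 alternatives AGO3 and rhi kept their calls, while tapas and aub lost theirs in 8, cuff and Nxf3 in 6, moon in 4, del and krimp in 2 and spn-E in 1, and with GFP dsRNA libraries in place of the untreated ones aub (−1.72) and cuff (−0.12) reversed. tej, BoYb (1.13 ± 0.56 SE) and Nbr (−0.85 ± 0.26 SE, adjusted p = 0.0503) were not called, but Nbr was called lower in 8 of 14 alternatives (adjusted p down to 0.00167) and BoYb higher in 1.

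Transcripts of piRNA clusters were a class chosen after its values were seen. The plus strand of flamenco, the main cluster of the ovarian soma, stood at 131 and 483 CPM in the libraries labelled WRR-1 and at 8.71 and 9.69 CPM in RasV12 (5.06 ± 0.67 SE, adjusted p = 0.00371). It stood at 1200 CPM in OSS, 1000 CPM in the library labelled ovary and 930 and 927 CPM after GFP dsRNA. The plus strand of 42AB, a germline cluster, was 2.38-fold higher than in RasV12 (1.25 ± 0.30 SE, adjusted p = 0.0251). Of 36 cluster strands tested, 13 were higher, 2 lower and 21 not called.

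Of 24 lists of genes fixed before the data were examined, 7 were called between the libraries labelled WRR-1 and RasV12, and each of these calls was lost with an estimated correlation (adjusted p = 0.602). That setting called 0 of 120 pairs of list and comparison, whatever their main value. Its losses, here and below, therefore do not tell stronger lists from weaker ones. Besides the germline piRNA factors, the list of DNA replication genes was lower in the libraries labelled WRR-1, with 13 of 25 members lower, 0 higher and 12 not called (adjusted over the list alone, 1 higher and 17 lower; adjusted p = 3.94e-07). It included the helicase genes Mcm7 (−2.34 ± 0.42 SE) and Mcm2 (−2.44 ± 0.46 SE) and the primase gene Prim2 (−2.21 ± 0.39 SE, listed as DNApol-alpha60). Of 22 hemocyte genes 9 were lower, 0 higher and 13 not called (adjusted over the list alone, 1 higher and 12 lower; adjusted p = 0.000212). Of 16 epithelium genes 10 were higher, 0 lower and 6 not called (adjusted over the list alone, 10 higher; adjusted p = 0.00273), among them ed (4.38 ± 0.33 SE), the polarity gene crb (5.43 ± 0.47 SE) and the E-cadherin gene shg (3.84 ± 0.51 SE). Of 21 Hippo pathway genes 12 were higher, 0 lower and 9 not called (adjusted over the list alone, 13 higher; adjusted p = 0.0144), including the cadherin genes ft (3.11 ± 0.36 SE) and ds (3.88 ± 0.52 SE). Of 21 Ras and MAPK genes 9 were higher, 0 lower and 12 not called (adjusted over the list alone, 10 higher; adjusted p = 0.0219), including vn (5.68 ± 0.70 SE), edl (2.84 ± 0.40 SE) and the EGFR inhibitor gene aos (2.24 ± 0.29 SE, listed as argos). Of 12 chorion and yolk genes 4 were higher, 0 lower and 8 not called (adjusted over the list alone, 5 higher; adjusted p = 0.0144).

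Among the lists that were not called, ovarian soma had 7 of 21 members higher and 2 lower (adjusted over the list alone, 7 and 2; adjusted p = 0.115), and germline 8 of 24 higher and 3 lower (12 and 3; 0.196). The piRNA lists for shared and somatic factors had adjusted p of 0.369 and 0.332, the latter with 1 of 3 members higher in both counts. Small RNA genes outside the piRNA pathway had 2 of 8 higher, namely Dcr-2 (2.86 ± 0.35 SE) and AGO1 (1.48 ± 0.39 SE), and 1 lower, loqs (−1.37 ± 0.35 SE), with the same 2 and 1 in the list alone (0.931). Muscle had 4 of 22 higher and 2 lower (4 and 2; 0.534). Neural genes had 5 of 17 higher (5 and 0; 0.138), including cpo (7.78 ± 0.72 SE). Fat body had 1 of 11 higher and 1 lower (1 and 0; 0.704). JAK/STAT had 3 of 13 higher (3 and 0; 0.311), including the transcription factor gene chinmo (3.97 ± 0.43 SE). JNK had 5 of 19 higher and 1 lower (6 and 1; 0.244), and immune genes 5 of 13 higher and 2 lower (5 and 3; 0.881). Ecdysone genes had 5 of 19 higher and 1 lower (12 and 2; 0.154), including Cyp18a1, which degrades the hormone (10.16 ± 0.68 SE), and, lower, Eip93F (−5.41 ± 0.83 SE; −0.52, adjusted p 0.533, with GFP dsRNA libraries in place of the untreated ones). Mitosis had 3 of 22 higher and 6 lower (3 and 7; 0.127), and heat shock 2 of 14 higher (2 and 0; 0.741). Dosage and sex genes had 3 of 10 higher and 2 lower (4 and 2; 0.613), the latter including roX2 (−3.58 ± 0.69 SE). Glycolysis had 1 of 12 higher and 1 lower (2 and 2; 0.182), and extracellular matrix 3 of 16 higher and 6 lower (3 and 6; 0.182).

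In total 2026 genes were higher and 1275 lower in the libraries labelled WRR-1 than in RasV12, 3301 at an adjusted p below 0.05. snoRNAs and rRNA features moved with the groups, with 83 of 218 and 34 of 84 lower in the libraries labelled WRR-1 and none higher. The count was 1010 without WRR-1 replicate 1 and 987 without replicate 2, 5435 without RasV12 replicate 1, and 1794 and 2076 without GFP dsRNA replicates 1 and 2. Of 84 named and called genes, 30 lost their call without either WRR-1 replicate, 14 and 10 without GFP dsRNA replicates 1 and 2, and 8 without RasV12 replicate 2. With RLE factors the median log2 fold change moved from 0.434 to 0.324 here, from 0.055 to −0.412 against OSS, from −0.763 to −1.125 for RasV12 against OSS and from 0.014 to 0.262 for GFP dsRNA. The p-values of these comparisons measured the spread between these samples alone, and the RasV12 pair differed in line and passage as well. Each of the 30 list calls made over 5 comparisons was lost with an estimated correlation (adjusted p = 0.602).

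The comparison with OSS asked how the libraries labelled WRR-1 differed from an ovarian somatic line. Glycolysis genes were higher than in OSS, with 10 of 12 members called, 0 lower and 2 not called (adjusted over the list alone, 11 higher; camera adjusted p = 1.39e-05; adjusted p = 0.602 with an estimated correlation). Ald1 (listed as Ald) stood at 844 and 836 CPM against 81.4 CPM (3.37 ± 0.45 SE, adjusted p = 0.0151, n = 2 and 1), and Eno at 751 and 685 CPM against 94.5 CPM (2.93 ± 0.45 SE, adjusted p = 0.0188). The Ras and MAPK list had 6 of 21 members higher, 0 lower and 15 not called (adjusted over the list alone, 8 higher; camera adjusted p = 0.0463; adjusted p = 0.602 with an estimated correlation). aos stood at 381 and 351 CPM against 3.53 CPM (6.69 ± 0.50 SE, adjusted p = 0.00497), and the Ets regulator gene edl (4.08 ± 0.57 SE), the receptor signalling inhibitor gene sty (2.93 ± 0.47 SE), the Ets factor gene pnt (2.95 ± 0.64 SE) and Ras85D itself (3.63 ± 0.64 SE, adjusted p = 0.0262) were higher with it. Muscle genes were lower, with 3 of 22 called, 0 higher and 19 not called (3 in the list alone; camera adjusted p = 0.0281; adjusted p = 0.602 with an estimated correlation), among them the nesprin gene Msp300 (−3.41 ± 0.45 SE) and Mef2 (−2.61 ± 0.41 SE).

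Both germline PIWI genes were higher than in OSS. aub stood at 6.51 CPM in OSS (4.32 ± 0.48 SE, adjusted p = 0.0106) and AGO3 at 8.49 CPM (3.35 ± 0.72 SE, adjusted p = 0.0398). The call of AGO3 was lost in 7 of 13 alternatives, among them RLE factors (adjusted p 0.0502) and the filter on CPM of at least 1 in at least 2 libraries, with adjusted p up to 0.138. That of aub was lost without WRR-1 replicate 1 (0.0734) or 2 (0.0603), and with GFP dsRNA libraries in place of the untreated ones its log2 fold change was 1.51 (0.117). piwi, at 711 CPM in OSS, was not called (−0.70 ± 0.60 SE, adjusted p = 0.404), nor was zuc (2.58 ± 0.64 SE, adjusted p = 0.0527). The plus strand of flamenco was not called (−1.96 ± 0.66 SE, adjusted p = 0.092), while that of 42AB was lower (−2.31 ± 0.35 SE, adjusted p = 0.0176), and 8 of 36 cluster strands were lower and 1 higher. The receptor gene mthl8, with 0 counts in OSS, was at least 126-fold higher, and the homeobox gene btn had a ratio of 1100 (349 to 10400). roX2, a noncoding RNA of dosage compensation, was 141-fold higher. The proneural gene sc had 1 count in the libraries labelled WRR-1 and was lower by a ratio of 1740 (457 to 101000). js (listed as CG14880), alpha-Est1, Ir47a and disco-r were lower too, by ratios between 763 and 1170. The Hippo target fj was 68.3-fold lower, and Myc (listed as dm) 5.45-fold lower.

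Called were 1057 genes, 648 higher and 409 lower, on the assumption that the lone OSS library varied like the other groups. With RLE factors 259 were higher and 571 lower, a share higher of 31.2% against 61.3%. No gene was called by edgeR without WRR-1 replicate 1 (3046 at an unadjusted p below 0.05) or replicate 2 (4500), while DESeq2 called 2427 with all libraries, and all 46 named genes called lost their call in both cases. The count was 4382 and 4265 without RasV12 replicates 1 and 2, and 312 and 445 without GFP dsRNA replicates 1 and 2, where 24 and 21 of the 46 lost their call.

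The RasV12 lines were set against OSS as well, to give the other side of that comparison. tj was lower in RasV12 by a ratio of 27600 (3810 to 839000), and Wnt4 at least 851-fold lower. piwi was 223-fold lower (−7.79 ± 0.70 SE, adjusted p = 0.00173, n = 2 and 1), rhi lower by a ratio of 267 (80.3 to 2440), armi 6.10-fold and AGO3 6.64-fold lower, and aub 9.42-fold higher. roX2 was 1690-fold, twi 516-fold and NimC4 244-fold higher, and Ras85D was 10.7-fold higher (3.41 ± 0.63 SE, adjusted p = 0.00903). Called lists, each lost with an estimated correlation (adjusted p = 0.602), were glycolysis (11 of 12 higher, also 11 in the list alone; 3.5e-05), DNA replication (8 of 25 higher and 2 lower, 9 and 2 in the list alone; 0.00238) and extracellular matrix (7 of 16 higher, 8 in the list alone; 0.0219). Of these 7 called lists, chorion and yolk (4 of 12, 4 in the list alone; 0.0144), neural (7 of 17, 11 in the list alone; 0.0247), ovarian soma (13 of 21 and 1 higher, 13 and 1 in the list alone; 0.029) and muscle (9 of 22 and 2 higher, 10 and 2 in the list alone; 0.0415, and 0.0534 with RLE factors) were lower. Of the snoRNAs 92 of 218 and of rRNA features 30 of 84 were higher. In all 5378 genes were called, 2524 of them higher, on the same assumption for OSS. The share higher was 46.9%, and 34.8% with RLE factors. The count was 3032 and 3315 without GFP dsRNA replicates 1 and 2, where 8 and 5 of 84 named and called genes lost their call.

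The library labelled ovary served as the tissue reference of the design. Its levels of germline, chorion and yolk genes ranged widely. The germ plasm gene osk stood at 0.0626 CPM, nanos at 0.156 CPM, the chorion gene Cp36 and bcd at 0 CPM, and the yolk protein genes Yp1 and Yp2 at 0.0939 and 0.188 CPM. Of 39 germline, chorion and yolk genes, 21 lay below 1 CPM, 7 lay over 20 CPM and 0 lay over 8 times above the highest cell line library. dec, an eggshell gene of follicle cells, stood at 176 CPM, tj at 815 CPM, and abd-A at 271 CPM. Its Spearman correlation across 13163 features was 0.955 with either GFP dsRNA library and 0.935 and 0.947 with the untreated ones, against 0.966 between the untreated pair. Correlations with OSS were 0.763 to 0.893 for all other libraries, and 0.938 between R3 and R7. These correlations run across features, which are not independent replicates. It is called the library labelled ovary throughout, and differences from it are not read as differences from ovary tissue.

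**Figure D2:**
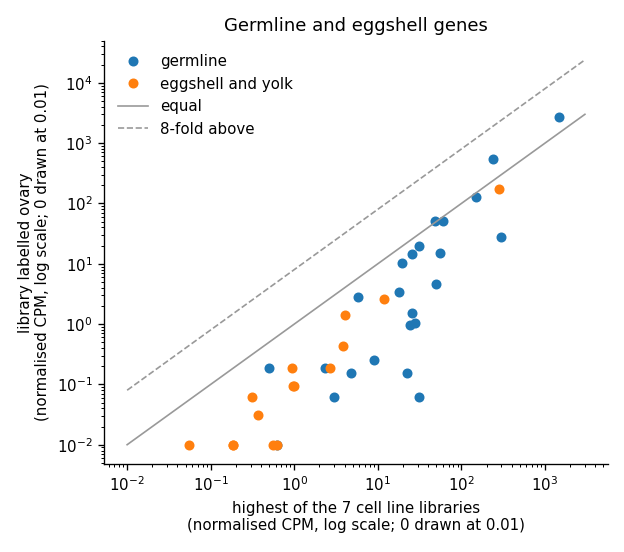
Normalised CPM of the 39 germline, chorion and yolk genes in the library labelled ovary against the highest of the 7 cell line libraries, both on log axes with 0 drawn at 0.01. Each point is 1 gene, and none lies above the dashed line that marks 8 times the cell line level.

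Compared with that library, the untreated libraries labelled WRR-1 had higher levels of NtR, a ligand-gated channel gene (6.33 ± 0.84 SE, adjusted p = 0.0495, n = 2 and 1), the ubiquitin ligase gene hiw (4.36 ± 0.50 SE, adjusted p = 0.0486), aub (3.64 ± 0.46 SE, adjusted p = 0.0486) and Sur (3.35 ± 0.46 SE, adjusted p = 0.0495). The matrix gene loh (listed as CG6232) was lower (−5.91 ± 0.43 SE, adjusted p = 0.00918), as were nAChRalpha3 (listed as nAcRalpha-7E), the activin ligand gene daw, Hsp67Bc and the stress RNA Hsromega. With GFP dsRNA libraries in place of the untreated ones all 9 calls were lost, and the log2 fold changes were 0.90 for NtR, 0.93 for hiw, 0.83 for aub and 2.32 for Sur. They were −3.53 for loh, −0.15 for nAChRalpha3, −4.79 for daw, −5.13 for Hsp67Bc and −1.85 for lncRNA:Hsromega. piwi, armi, zuc, AGO3, wts and Ras85D were not called, with adjusted p between 0.472 and 0.981.

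DNA replication genes were higher than in the library labelled ovary as a list, with 0 of 25 members called and 20 higher when adjusted over the list alone (camera adjusted p = 4.63e-10; adjusted p = 0.602 with an estimated correlation). Mitosis genes were higher with 0 of 22 called (5 in the list alone; 0.000424), and germline piRNA factors with 1 of 13 called, aub (3 higher and 1 lower in the list alone; 0.0463). Heat shock (0 of 14 called, 6 lower in the list alone; 5.64e-05), glycolysis (0 of 12, 3 lower; 0.004), ecdysone (1 of 19 lower, 8 lower; 0.004), and Hippo genes (0 of 21, 6 lower; 0.0144) were lower as lists. The Ras and MAPK list was called by camera (0.0281) with 0 of 21 members called and 1 higher and 1 lower in the list alone. Each of the 8 list calls was lost with an estimated correlation (0.602), and fry gave 0.147 for Ras and MAPK, 0.0961 for heat shock and 0.0503 for both glycolysis and germline piRNA factors. Of all genes 35 were called, 8 higher and 27 lower, with 2002 at an unadjusted p below 0.05. The count was 86 with RLE factors, 1131 with DESeq2, 1277 and 1358 without RasV12 replicates 1 and 2 and 2 without GFP dsRNA replicate 1. It was 0 in edgeR without WRR-1 replicate 1 (1371 at an unadjusted p below 0.05) or replicate 2 (1929). Of 9 named and called genes followed in this way, all 9 lost their call in both cases, and 8 and 2 without GFP dsRNA replicates 1 and 2.

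GFP dsRNA libraries were compared with the untreated libraries labelled WRR-1 to see what a control dsRNA brings with it. Their culture passage was not given, so an effect of dsRNA and a difference of passage cannot be told apart. The eye pigment transporter gene w stood at 1900 and 1680 CPM after GFP dsRNA and at 97.0 and 88.0 CPM without (4.27 ± 0.35 SE, adjusted p = 0.0217, n = 2 and 2). The Notch target genes E(spl)m7-HLH (listed as HLHm7; 6.20 ± 0.80 SE) and E(spl)mbeta-HLH (listed as HLHmbeta; 4.74 ± 0.55 SE), Syx4, nAChRalpha3 and Eip93F (4.89 ± 0.81 SE) were higher too. Lower were the meiosis gene cona (−6.78 ± 1.05 SE), the SKP1 paralogue SkpC (−6.49 ± 0.66 SE), the ribosomal protein gene RpS5b (−6.30 ± 0.82 SE), NtR (−5.44 ± 0.58 SE) and the neuropeptide gene Ptth (−5.05 ± 0.57 SE). aub, at 18.4 and 18.7 CPM after GFP dsRNA, was 7.01-fold lower (−2.81 ± 0.33 SE, adjusted p = 0.024). piwi (0.80 ± 0.50 SE), armi, zuc, AGO3, wts (0.23 ± 0.27 SE) and Ras85D (−0.27 ± 0.43 SE) were not called.

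Glycolysis genes were lower in the GFP dsRNA libraries as a list, with 0 of 12 members called and 8 lower when adjusted over the list alone (camera adjusted p = 0.00141; adjusted p = 0.602 with an estimated correlation). In the authors' deposited table labelled dsRED, 2 of 12 were higher and 0 lower. Ovarian soma (1 of 21 lower; 5 higher and 1 lower in the list alone; 0.0144), neural (1 of 17 lower; 3 higher and 1 lower; 0.0274), epithelium (0 of 16; 2 higher; 0.0281) and ecdysone genes (2 of 19 higher; 6 higher; 0.0463) were higher as lists, each with 0.602 at an estimated correlation. Called were 145 genes, 70 higher and 75 lower, with 3107 at an unadjusted p below 0.05. The count was 302 with RLE factors, of which 73.8% were higher against 48.3%, and 1608 with DESeq2. It was 2598 and 2370 without RasV12 replicates 1 and 2, and 1 and 12 without GFP dsRNA replicates 1 and 2. edgeR called 0 genes without WRR-1 replicate 1 (1426 at an unadjusted p below 0.05) or replicate 2 (3256). Of 11 named and called genes, all 11 lost their call without either WRR-1 replicate or without GFP dsRNA replicate 1, and 6 without GFP dsRNA replicate 2.

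The knock-down tables were deposited by the authors as means of 2 libraries per group, so no test or spread per library could be computed from them. They addressed what loss of a piRNA factor does to gene expression in cells labelled WRR-1. All 6 tables used the same untreated control pair, of passages 111 and 112. In the authors' deposited table labelled piwi, piwi itself had a mean of 11910 against 27970 normalised counts in the control (log2 fold change −1.10 ± 0.21 SE, adjusted p = 1.85e-05). The targeted gene went against the label in the other authors' deposited tables, with zuc at 40820 against 445.9 (6.32), aub at 13040 against 77.47 (6.12), AGO3 at 126100 against 277.7 (8.47) and armi at 32160 against 15120 (1.06 ± 0.14, adjusted p = 2e-12). zuc, aub and AGO3 had the largest rise of their own tables, and armi ranked 221. The deposited log2 fold changes can be smaller in size than the ratio of the means beside them. For aub that ratio was 168, and Muc12Ea in the dsRED table had −1.92 with means of 8.823 against 279.2. Comparisons between tables and counts above a fold rest on the deposited values. These tables are therefore named by their labels, and a direction in them is not read as an effect of losing the gene.

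**Figure D3:**
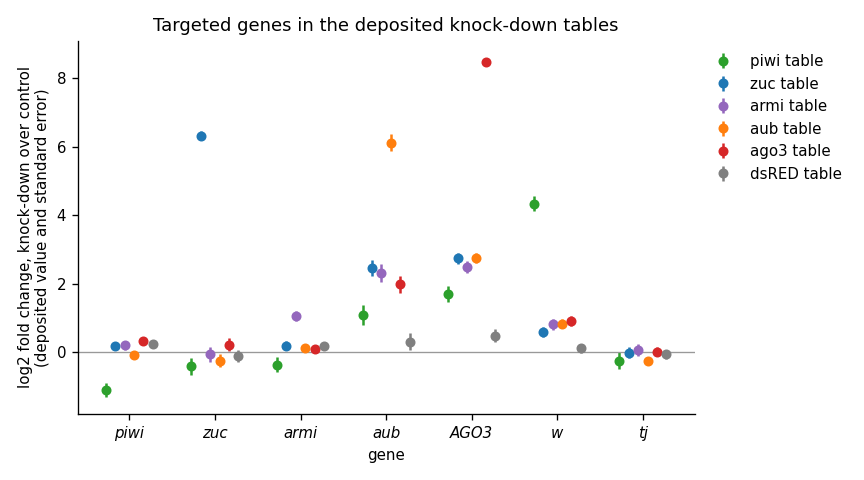
Log2 fold changes of 7 genes in the authors' 6 deposited knock-down tables, with bars for the deposited standard error and 1 point per table. piwi is lower in the piwi table (−1.10), whereas zuc (6.32), aub (6.12) and AGO3 (8.47) are highest in the tables that bear their names.

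In the authors' deposited table labelled piwi, the largest rises were w, at 70180 against 2265 normalised counts (4.34), CG32795 (4.09) and the uridylyltransferase gene Tailor (3.76, listed as CG1091). w had 0.59, 0.82, 0.84 and 0.91 in those labelled zuc, armi, aub and ago3, and 0.12 in dsRED. It was also called higher in the GFP dsRNA libraries, but against another untreated pair than the control of these tables. In dsRED, which shares that control, w was not called (authors' adjusted p = 0.501). The call with GFP dsRNA therefore does not show that control dsRNA gave the rise of w in the piwi table. Whether that rise is an effect of losing piwi was not tested, and it is not read as one. kel, which organises ring canals, was higher in the authors' deposited tables labelled piwi (1.83), zuc (1.88) and armi (2.41), and had 0.16, −0.07 and 0.44 in those labelled aub, ago3 and dsRED. Oat had 1.93, 2.45 and 2.70 in the authors' deposited tables labelled piwi, zuc and armi, and 0.53, 0.64 and −0.33 in those labelled aub, ago3 and dsRED. atk (listed as CG5195) was lower in the authors' deposited tables labelled piwi (−2.61), zuc (−3.47), armi (−3.06), aub (−2.74) and ago3 (−2.28), and had 0.38 in that labelled dsRED. AGO3 had 1.70, 2.74, 2.49 and 2.76 in the authors' deposited tables labelled piwi, zuc, armi and aub, and 0.49 in that labelled dsRED. aub had 1.08, 2.46, 2.32 and 1.99 in those labelled piwi, zuc, armi and ago3 of the authors' deposited tables, and 0.31 in dsRED. Of these smaller values, some were called higher too. They were kel (authors' adjusted p = 0.000476), atk (0.0284) and AGO3 (0.0411) in dsRED, and Oat in ago3 (0.0178). The glutathione transferase gene GstT4 (listed as CG1681) had 2.89, 2.93 and 2.28 in the authors' deposited tables labelled zuc, armi and ago3. Obp99a, an odorant-binding protein gene, had 3.45, 2.74 and 2.43 there, and the growth factor gene Pvf1 had 2.71 and 2.52 in those labelled armi and ago3.

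In the authors' deposited table labelled aub, 13 of 14 heat shock genes were higher and 1 lower, including Hsp68 (5.06), Hsp70Bc (4.21) and Hsp26 (3.85), and the cognate gene Hsc70-4 was lower (−2.57). In the authors' deposited tables labelled zuc, armi and ago3, 5, 6 and 7 of 12 were higher and 2, 1 and 1 lower, and in that labelled dsRED 7 of 14 were higher, with Hsp68 at 2.26. In that labelled piwi 0 of 10 were higher and 4 lower. Glycolysis members were lower in the authors' deposited tables labelled zuc (7 of 12), armi (5), ago3 (5) and aub (2), with 0 called in piwi and 2 higher in dsRED. Of 21 Hippo genes 7, 8, 8, 10 and 9 were higher in the authors' deposited tables labelled zuc, armi, aub, ago3 and dsRED, with 1 lower in aub, and 3 of 20 were higher in that labelled piwi. snRNA:U4:38AB had −2.67, −3.09, −2.79, −2.56 and −3.09 in those labelled piwi, zuc, armi, aub and ago3, and −1.31 in dsRED. Of the snoRNAs, 73 of 114, 60 of 144, 82 of 149, 67 of 158 and 63 of 145 were lower in the authors' deposited tables labelled piwi, zuc, armi, aub and ago3, and 87 of 170 in that labelled dsRED.

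At the authors' adjusted p below 0.05, their deposited tables held 485 genes for piwi (191 higher, 294 lower), 1581 for zuc (956, 625), 1733 for armi (1019, 714), 1928 for aub (1142, 786), 1480 for ago3 (896, 584) and 2870 for dsRED (1526, 1344). With an absolute log2 fold change above 1, lower genes prevailed in each of the authors' deposited tables, with 110 higher and 154 lower for piwi, 206 and 327 for zuc, 248 and 441 for armi, 164 and 243 for aub, 110 and 179 for ago3 and 30 and 222 for dsRED. Tables labelled zuc and armi shared 728 higher genes, where 102 would be shared by independent lists, and 430 lower genes, where 47.0 would be. Those labelled piwi and zuc shared 149 against 22.1 and 190 against 20.5, and those labelled piwi and dsRED 52 against 36.0 and 85 against 20.6. In the authors' deposited tables labelled piwi, zuc and armi, 139 genes were higher and 182 lower in all 3. In those of the 5 factors, 101 were higher and 150 lower in all 5. Of these, dsRED had 39 and 57 called in the same direction and 3 and 9 in the opposite one. Because the tables shared their control libraries, independent lists are no fair background. Simulated groups without a change, set against shared controls, gave at most 0 shared calls and Spearman correlations across genes of 0.47 to 0.48, against 0.90 for zuc with armi, 0.62 for piwi with zuc and 0.06 for piwi with dsRED. The simulation assumed that the shared controls gave as much variance as the knock-down libraries, which set its correlations and covariances. Groups without a change give next to no calls, so the 0 shared calls were fixed in advance. The covariance of log2 fold changes was 0.259 for zuc with armi (0.0332 simulated) and 0.0166 for piwi with dsRED (0.0216 simulated). The control table labelled dsRED shared more with the other authors' deposited tables, with covariances of 0.101 for zuc, 0.126 for armi, 0.109 for aub and 0.0925 for ago3 (0.0228, 0.0257, 0.0212 and 0.0203 simulated). It shared 366 higher genes with armi, where 152 would be shared by independent lists, and 328 lower genes, where 90.5 would be. The control pair could not be split between tables, since only its means were deposited, so the excess is not read as a shared effect.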

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

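The fits on mRNA features only and without the library labelled ovary were chosen after seeing the data. All other alternatives were planned. Where a group was left with 1 library, it was assumed to vary like the other groups. The cause was not tested for any change in this part, except that a stricter threshold or a minimum fold calls fewer genes by construction.

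For the libraries labelled WRR-1 against RasV12, 3301 genes were called. Leaving out replicates gave 987 to 5435, with 5435 without RasV12 replicate 1, 1010 and 987 without WRR-1 replicates 1 and 2, and 1794 and 2076 without GFP dsRNA replicates 1 and 2. Only the 4 libraries compared gave 1510, GFP dsRNA libraries in place of the untreated ones 5491, and an adjusted p below 0.01 gave 756. RLE factors (3385), the DESeq2 Wald test (4707) and either other filter (3431 and 3678) stayed within 1.5 times.

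Against OSS 1057 genes were called by edgeR. Leaving out replicates gave 0 to 4382, with 0 without WRR-1 replicate 1 (3046 at an unadjusted p below 0.05) or replicate 2 (4500), 312 and 445 without GFP dsRNA replicates 1 and 2, and 4382 and 4265 without RasV12 replicates 1 and 2. The DESeq2 Wald test gave 2427, CPM of at least 1 in at least 2 libraries 508, GFP dsRNA libraries in place of the untreated ones 330, and an adjusted p below 0.01 gave 34.

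Against the library labelled ovary 35 genes were called by edgeR. Leaving out replicates gave 0 to 1358, with 0 without WRR-1 replicate 1 (1371 at an unadjusted p below 0.05) or replicate 2 (1929), 2 without GFP dsRNA replicate 1, and 1277 and 1358 without RasV12 replicates 1 and 2. RLE factors gave 86, the DESeq2 Wald test 1131, no filter on low counts 154, CPM of at least 1 in at least 2 libraries 2, mRNA features only 136, and an adjusted p below 0.01 gave 2. GFP dsRNA libraries in place of the untreated ones gave 0 (1181 at an unadjusted p below 0.05). For RasV12 against OSS, with 5378 genes called, leaving out replicates gave 3032 to 6464, with 3032 and 3315 without GFP dsRNA replicates 1 and 2, and an adjusted p below 0.01 gave 1387.

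For GFP dsRNA against untreated libraries 145 genes were called by edgeR. Leaving out replicates gave 0 to 2598, with 0 without WRR-1 replicate 1 (1426 at an unadjusted p below 0.05) or replicate 2 (3256), 1 and 12 without GFP dsRNA replicates 1 and 2, and 2598 and 2370 without RasV12 replicates 1 and 2. RLE factors gave 302, the DESeq2 Wald test 1608, no filter on low counts 353, CPM of at least 1 in at least 2 libraries 252, only the 4 libraries compared 2686, mRNA features only 331, and an adjusted p below 0.01 gave 1. With a replicate block on the 4 libraries compared, 1514 were called. The labels give no reason to pair replicates, and deviations of replicates correlated across genes at 0.07 between these groups, and at −0.07 and 0.05 between the other pairs of groups.

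Of 30 list calls, camera with estimated correlation kept 0 (lowest adjusted p 0.602). It called 0 of 120 pairs of list and comparison, so it does not tell the lists apart. fry made 46 calls and shared 21 of the 30, and RLE factors kept 29.

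Among named genes, 247 of 262 kept direction and side of the threshold with RLE factors, 256 with the DESeq2 Wald test, 262 with no filter and 230 of 255 with CPM of at least 1 in at least 2 libraries. Without WRR-1 replicate 1 or 2 this held for 160 each, with 96 no longer called in each case, and without GFP dsRNA replicates 1 and 2 for 197 and 215. Without RasV12 replicates 1 and 2 it held for 251 and 246. It held for 96 of 117 on only the 4 libraries compared, 110 of 162 with GFP dsRNA libraries in place of the untreated ones, 251 of 258 on mRNA features only and 250 of 251 without the library labelled ovary.

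Against RasV12, uncalled genes reversed, most of them with a log2 fold change near 0. zuc gave −0.05 with RLE factors and with DESeq2, −0.08 with CPM of at least 1 in at least 2 libraries, 0 on only the 4 libraries compared and −0.01 on mRNA features only. shu gave −0.07, −0.07, −0.1, −0.02 and −0.03 in the same order, and squ −0.06, −0.06, −0.08, −0.03 and −0.04. Leaving out replicates gave ranges across 0 for zuc (−0.47 to 0.84), vret (−0.13 to 0.53), shu (−0.38 to 0.56), arx (−0.66 to 0.75), egg (−0.33 to 0.06), wde (−0.22 to 0.8), mino (−0.64 to 0.25), squ (−0.31 to 0.45), daed (−0.4 to 0.22), fs(1)Yb (−0.84 to 0.04), SoYb (−0.03 to 1.69) and Ras85D (−0.21 to 0.79). For GFP dsRNA against untreated libraries Ras85D ranged from −0.43 to 0.02.

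With GFP dsRNA libraries in place of the untreated ones, the called gene aub reversed against RasV12 to −1.72 and stayed past the threshold (adjusted p 0.00565, over all its alternatives 0.00565 to 0.219). cuff (−0.12), Appl (−0.13) and tra (−0.17) reversed and were no longer called, and zuc (−1.1), vret (−0.86), nxf2 (−0.35) and Ras85D (−0.05) reversed without a call in either setting. Against OSS, ct (−1.41), Eip93F (0.09), stv (0.18) and piwi (0.1) reversed.

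In the authors' deposited tables labelled piwi, zuc, armi, aub, ago3 and dsRED, an adjusted p below 0.01 gave 311, 950, 1028, 1151, 813 and 1322 genes, and a log2 fold change above 1 in size 264, 533, 689, 407, 289 and 252. At 0.01, piwi shared 217 with zuc, 237 with armi, 181 with aub, 185 with ago3 and 83 with dsRED. zuc shared 702 with armi, 578 with aub, 619 with ago3 and 219 with dsRED, and armi 608 with aub, 606 with ago3 and 299 with dsRED. aub shared 611 with ago3 and 302 with dsRED, ago3 shared 207 with dsRED, and piwi, zuc and armi shared 205. Another pseudocount, another tool, leaving out libraries and pairing were not run on these tables, since only group means were deposited.

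Depth limited genes without counts, whose folds are lower bounds from a floor of 3 counts per library, at 0.0426 to 0.191 CPM. In simulated data of the same design 59.7% of 4-fold changes were recovered against RasV12 and 28.4% against OSS, where depth and the single library were not told apart.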

Other observations

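All tests in this part were chosen after the result was seen, except the correlation with the difference between the passage 154 and GFP dsRNA libraries, whose bound was written before, and whose explanation was narrowed in wording afterwards.

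Most germline, chorion and yolk genes (21 of 39) lay below 1 CPM in the library labelled ovary, while 7 lay over 20 CPM. Too few reads in the library are argued against, since 3 counts lay at 0.0939 CPM. A mislabelled sample cannot be told apart, since the test (0 of 39 genes over 8 times above the highest cell line library) restates the pattern. The library's Spearman correlation was 0.955 with either GFP dsRNA library, against 0.966 between the untreated pair labelled WRR-1. A mislabelled sample would give such values, but they do not decide it. An ovary that held follicle cells only cannot be told apart either, since Ras85D, 3.88 ± 0.68 SE above OSS on the log2 scale with a spread borrowed from the other groups, has no ovary without the transgene as a baseline. No biological explanation was tested.

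The targeted gene was higher, not lower, in its own table for zuc, aub, AGO3 and armi. That 4 of 4 targets had their largest rise in their own table restates the pattern. Knock-down libraries exchanged between tables would put a fall of these targets in another table. The lowest values were −0.41 for zuc and −0.36 for armi, both in the piwi table (authors' adjusted p 0.455 and 0.464). aub and AGO3 lay at 0.31 and 0.49 or more in all tables, so an exchange among these targets is argued against. Reads from the transfected dsRNA cannot be told apart from a rise of the transcript, neither for zuc, aub and AGO3, where the largest rise in 3 of 3 tables restates the pattern, nor for armi, which ranked 221. Values by position, which would decide it, were not used here. No biological explanation was tested.

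aub and AGO3 were higher in the tables of other piRNA factors. dsRED dsRNA is argued against as giving the whole of the rise, since AGO3 in the dsRED table lay at 0.49 against 1.70 or more. dsRNA treatment of any kind cannot be told apart, since the GFP dsRNA libraries were not set against the control of these tables. AGO3 was called higher in the dsRED table as well (0.49 ± 0.19 SE, authors' adjusted p = 0.0411), so a smaller part may come with dsRNA. The difference that separates the passage 154 from the GFP dsRNA libraries cannot be told apart either. Its Spearman rho across genes was −0.14 with the mean of 5 tables, below the bound of 0.05 written before. It was −0.25 for piwi, 0.01 for zuc, 0.02 for armi and ago3, 0.12 for aub, which lies above that bound, and 0.19 for dsRED. A correlation across all genes does not decide what raised aub and AGO3. In that contrast aub went in the direction of the pattern (2.81) and AGO3 was not called (0.82, adjusted p 0.322). The control of the tables was also another untreated pair than that of passage 154. Reads carried over from the libraries richest in them cannot be told apart, since zuc, at −0.41 to 0.22 in other tables where the share needed for AGO3 (1.26%, against 2.81% for aub) would give 1.1, tests only the zuc libraries. Loss of a piRNA factor, which the design names, stays open and was not tested.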
